A study of Homo sapiens with 40 samples.

How the data were processed

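RNA was measured in 40 libraries of human microglia-like cells (hMGLs) made from H9 embryonic stem cells and isogenic clones: 7 of WT, 8 of TREM2-KO, 7 of TREM2-R47H, 7 of SORL1-KO, 7 of SORL1-A528T, 2 of CD33-SNP and 2 of INPP5D-SNP. Per the labels, haematopoietic progenitors were collected on day 11 and differentiated for 28 days with IL-34 (100 ng/mL), TGF-beta 1 (50 ng/mL) and M-CSF (25 ng/mL), and CD200 and CX3CL1 (100 ng/mL each) were added for the last 3 days. RNA with an integrity number of at least 9 was used at 500 ng for directional libraries, read as pairs of 150 bp. The labels name the INPP5D edit as a conversion of a polymorphism for which H9 is heterozygous. Groups came from the labels alone; whether replicates are separate cultures, and what their numbers stand for, is not given in the sources used here.

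The authors made the deposited TPM values, 1 column per library, and their processing notes name cutadapt 1.18, STAR 2.7, RSEM 1.3.1 and DESeq2, without a version for the last. The genome build and annotation are not given in the sources used here. Each column of the 60504 genes summed to between 999999.15 and 1000000.76, values had 2 decimals, and no scaling between libraries was seen. Read counts are not part of the deposited table, so depth per library and counting error could not be computed and no count model was used. Precision was read from the spread between libraries. Symbols were found for 93.5 percent of gene IDs, and positions are those of GENCODE release 29 (GRCh38), matched by Ensembl ID.

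Changes were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended and robust variance, in a single fit of all 40 libraries with the 7 groups as means and no rescaling. Genes with at least 1 TPM in at least 7 libraries were kept, which left 14855. P-values were two-sided and adjusted by Benjamini-Hochberg over the kept genes, and genes with adjusted p below 0.05 are called. Each edited line was compared with WT, and the lines of TREM2 and of SORL1 with each other. APOE and the edited genes also had two-sided exact permutation tests of log2(TPM + 1) over all splits of the 2 groups, adjusted over 6 comparisons for APOE.

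31 gene lists were fixed, and the 24 with at least 5 kept genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 7 lists not tested had 4 kept metallothioneins, 4 progenitor, 2 erythroid or megakaryocyte, 3 neutrophil, 2 pluripotent, 2 neural and 4 lymphoid markers; the highest group mean of any member was 12.9, 123, 2.65, 51.0, 4.67, 20.8 and 11.7 TPM in that order. Lists overlap (APOE is in 3), and several markers of other cells are also expressed by macrophages. The stromal score is the mean log2(TPM + 1) of the listed endothelial and stromal markers found among the deposited genes. It includes markers that the filter on low values dropped, whereas the list tests used the kept markers alone.

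The tests, lists, groups and most alternatives were chosen before the data were examined, as was the rule for naming genes. The rule takes the edited genes and APOE in every comparison, the called genes with the largest changes each way and at least 5 TPM in a group (10 each way against WT for lines with 7 or more libraries, 5 for the other lines, 8 between lines of a gene), with at most 1 library off the side of the change, and up to 4 members of each list with the lowest adjusted p. Other members of a list named in the text, and genes lost in a single line, were chosen after their values were seen. Some results are not reported here, and the tests of genes lost in a single line were recomputed without them.

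The alternatives fixed in advance were pseudocounts of 0.1 and 5 TPM, no filter and 2 other filters, median-ratio scaling, quantile normalization, fits of the 2 groups alone, the library number as a block, limma arrayWeights, a residual principal component as a covariate, and leaving out each library of the 2 small groups. Chosen after the data were seen were leaving out 3 libraries that stand apart, averaging libraries 5 and 6, the stromal score as a covariate, the block in fits of 2 groups, and libraries 1 to 3 alone. A number was taken to pair libraries where the correlation of their residuals was above 0.1 for every shared number.

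Sharing between lines was compared with the number for independent lists, with 100 sets in which residuals of the same libraries were dealt out without replacement, and with WT libraries split between the lines. The procedure was tested on simulated data with 200 genes changed: for 8 against 7 libraries 97 percent of genes changed by 1 on the log2 scale were recovered with 12 false calls (5.77 percent), and for 2 against 7 libraries 83 percent with 22 false calls (10.8 percent). Residuals were drawn separately for each gene, and the changed genes were not among those weakly expressed in WT. These rates therefore leave out the correlation between genes and between libraries and may not hold for the real data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for exact tests and figures.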

Results

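RNA was sequenced from human microglia-like cells, which are grown from pluripotent stem cells to resemble the resident macrophages of the brain. All of them came from H9, an established human embryonic stem cell line, and from H9 clones edited with CRISPR/Cas9 to carry variants associated with Alzheimer's disease on both alleles. The 40 libraries fell into 7 groups: 7 of unedited WT, 8 of TREM2-KO, 7 of TREM2-R47H, 7 of SORL1-KO, 7 of SORL1-A528T, 2 of CD33-SNP and 2 of INPP5D-SNP. The deposited values were TPM (RSEM transcript abundance scaled to the same total in each library) for 60504 genes, and each library had between 13208 and 14086 genes at 1 TPM or more. TPM keeps no read count, so the depth of a single library is unknown; the labels give a mean of 45.13 M reads, with 39.2 M and 64.6 M as the extremes. Nothing in the labels says whether libraries of a group came from separate clones or differentiations, so the p-values measure the spread between these libraries, which may be technical. Changes are log2 fold changes of TPM + 1 with limma's adjusted p, which understate the change of weakly expressed genes.

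The edited genes were examined first in every group. TREM2 (ENSG00000095970, GRCh38 chromosome 6, 41158506 to 41163186), a lipid receptor of microglia that signals through TYROBP, was at 457 ± 120 TPM in WT (SD, n = 7) and at 35.3 ± 8.39 TPM in TREM2-KO (SD, n = 8). The change was -3.64 ± 0.17 (SE; limma adjusted p = 8.9e-18), and TREM2 was below the WT mean in 8 of 8 TREM2-KO libraries (two-sided exact permutation p = 0.0003, the smallest that 8 against 7 libraries allow). In TREM2-R47H, whose edit changes the receptor's sequence, TREM2 was at 467 ± 83.4 TPM (SD, n = 7) and did not pass the test (0.06, limma adjusted p = 0.891). SORL1 (ENSG00000137642, chromosome 11, 121452203 to 121633693), a sorting receptor of the endosome, was lower in SORL1-KO, at 16.1 ± 3.00 TPM against 33.3 ± 9.74 TPM in WT (SD, n = 7 each). That change of -0.96 was called with limma adjusted p = 0.0462, but not without a filter on low values, with median-ratio scaling or with quantile normalization (limma adjusted p = 0.0942, 0.0536 and 0.0529); the two-sided exact permutation p was 0.00233. The labels name a stop-gain change of SORL1 among the edits and call the samples SORL1-KO, and RNA left at a lower level does not by itself report on protein. SORL1 was at 39.9 ± 13.7 TPM in SORL1-A528T (SD, n = 7; 0.23, limma adjusted p = 0.999). CD33 (ENSG00000105383, chromosome 19, 51225064 to 51243860), a sialic acid receptor, was at 56.1 ± 4.09 TPM in CD33-SNP (SD, n = 2) against 61.2 ± 8.60 TPM in WT. INPP5D (ENSG00000168918, chromosome 2, 233059967 to 233207903), an inositol phosphatase of immune cells, was at 132 ± 0.615 TPM in INPP5D-SNP (SD, n = 2) against 123 ± 6.15 TPM in WT. Neither of these passed the test, with changes of -0.11 and 0.10, and 2 against 7 libraries cannot reach an exact permutation p below 0.0556.

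**Figure D1:**
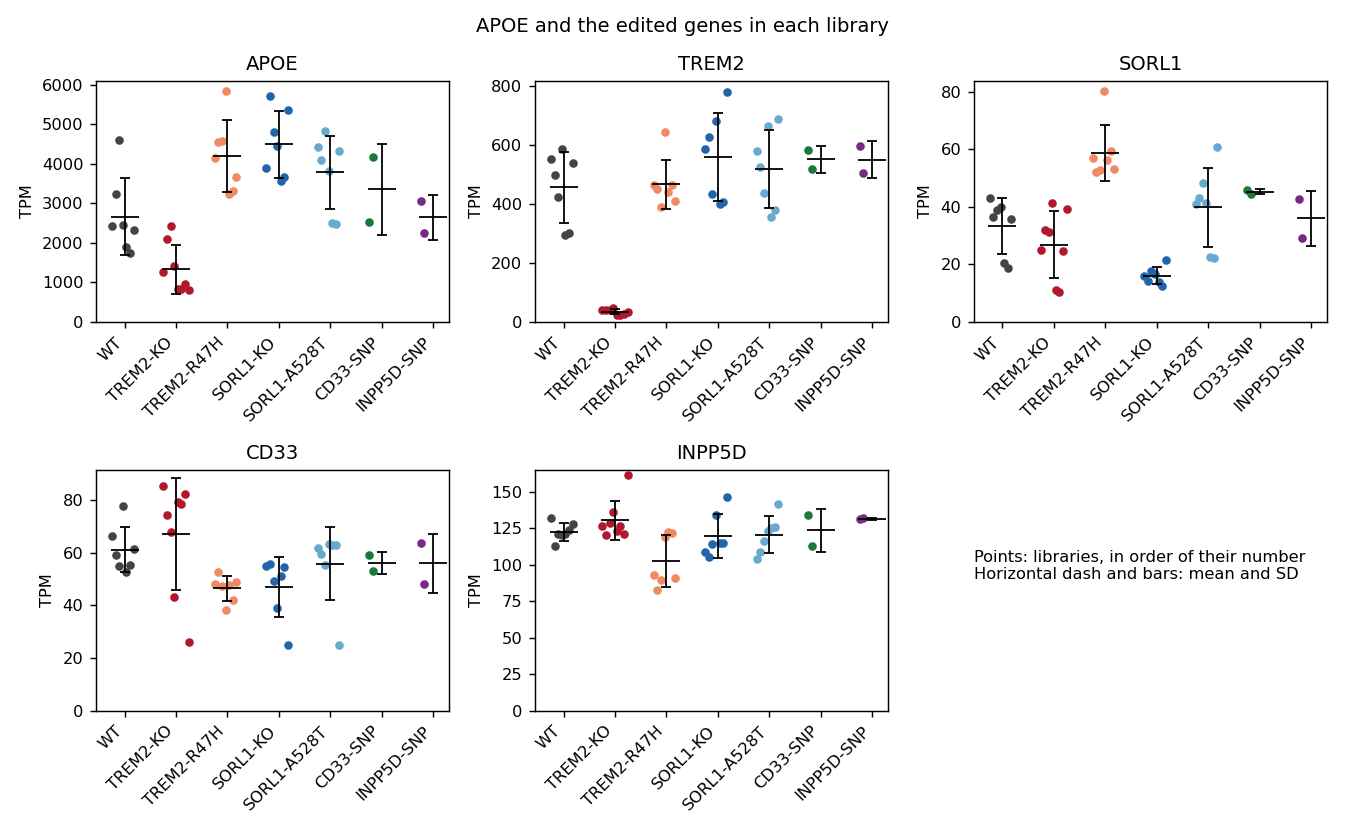
TPM of APOE, TREM2, SORL1, CD33 and INPP5D (vertical axes, linear from 0) in each of the 40 libraries, by group; points are libraries placed in order of their number, the dash is the group mean and the bars are the SD. TREM2 falls to 35.3 TPM in TREM2-KO, and the APOE means run from 1336 TPM in TREM2-KO to 4494 TPM in SORL1-KO.

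APOE (ENSG00000130203, chromosome 19, 44905754 to 44909393), a lipid carrier and the strongest common risk gene for late-onset Alzheimer's disease, is the gene at which the series title places a convergence of the variants. APOE fell in TREM2-KO, to 1336 ± 621 TPM (SD, n = 8) from 2669 ± 982 TPM in WT (SD, n = 7), a change of -1.05 ± 0.22 (SE; limma adjusted p = 0.00541). APOE rose in TREM2-R47H, to 4199 ± 907 TPM (SD, n = 7), a change of 0.70 ± 0.23 (SE; limma adjusted p = 0.0374), with 7 of 7 libraries above the WT mean. The SORL1-KO level was 4494 ± 839 TPM (SD, n = 7), a change of 0.80 with 7 of 7 libraries above the WT mean, which did not pass over all genes (limma adjusted p = 0.065). APOE was at 3783 ± 935 TPM in SORL1-A528T (SD, n = 7; 0.53, limma adjusted p = 0.642), at 3356 ± 1152 TPM in CD33-SNP and at 2653 ± 567 TPM in INPP5D-SNP (SD, n = 2 each; 0.36 and 0.05). The CD33-SNP change was 0.72 without replicate 1 and 0.0017 without replicate 2, and that of INPP5D-SNP -0.17 and 0.27. Two-sided exact permutation tests of these 6 comparisons, adjusted over the 6, gave p = 0.014 for TREM2-KO, 0.0186 for TREM2-R47H, 0.014 for SORL1-KO, 0.0682 for SORL1-A528T, 0.533 for CD33-SNP and 0.944 for INPP5D-SNP; the unadjusted p were 0.00435, 0.00932, 0.00466, 0.0455, 0.444 and 0.944. The TREM2-R47H call was lost with the stromal marker score as a covariate (0.39, limma adjusted p = 0.387), without a filter (adjusted p = 0.0831), with quantile normalization (adjusted p = 0.0893), with libraries 5 and 6 averaged (adjusted p = 0.0737) and with libraries 1 to 3 alone (adjusted p = 0.264). The TREM2-KO call was lost in a fit of its 2 groups alone (limma adjusted p = 0.0748) and with libraries 1 to 3 alone (-0.83, limma adjusted p = 0.145). It was kept with the library number as a block in the fit of the same 2 groups (-0.96, limma adjusted p = 0.000183) and of all libraries (limma adjusted p = 3.7e-05). The SORL1-KO change was called with the block in a fit of all libraries (limma adjusted p = 0.000718), with the block in the 2 groups (limma adjusted p = 0.0264) and with the residual component (limma adjusted p = 0.0262). With the stromal covariate it was 0.42 (limma adjusted p = 0.557), and in SORL1-A528T APOE had 0.18.

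The loss of TREM2 went with lower expression of genes that microglia raise around amyloid plaques. Of the 24 kept genes of the disease-associated microglia list, 8 fell and none rose in TREM2-KO. They included the secreted phosphoprotein SPP1, at 8424 ± 3560 TPM against 18604 ± 4600 TPM in WT (-1.33, limma adjusted p = 0.00846), the lysosomal glycoprotein GPNMB (-1.59), the lipoprotein lipase LPL (-1.45), the tetraspanin CD9 (-0.84) and the scavenger receptor MSR1 (-1.02). The apolipoproteins APOC1, at 176 ± 82.9 TPM against 529 ± 170 TPM, and APOC2 also fell, by 1.66 and 0.82 on the log2 scale, within an apolipoprotein and efflux list of 18 kept genes in which 4 fell. Adjusted over the list alone, 10 disease-associated genes and 4 apolipoprotein genes were lower. The disease-associated list was lower by limma's directional fry test (adjusted p = 0.0126) and by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.125 with an estimated correlation).

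Immediate early and heat shock genes formed another lower group in TREM2-KO, with 5 of 18 kept members called and none higher. EGR1, EGR2 and EGR3, transcription factors induced within minutes of a stimulus, fell by 1.44, 1.42 and 1.21 on the log2 scale, the phosphatase DUSP1 by 0.56 and the small heat shock protein HSPB1 by 0.72. This list kept its call with an estimated correlation (limma camera adjusted p = 0.0306 with an estimated correlation; fry adjusted p = 0.000555), and 9 members were lower adjusted over the list alone. The extracellular matrix and adhesion list also kept it (adjusted p = 0.0479 with an estimated correlation), with COL4A1, MMP2 and ITGB5 among 3 of 20 members lower, and 13 lower adjusted over the list alone. Stromal RNA moved with that list: the mean log2 value of the endothelial and stromal markers was 2.71 ± 1.54 in WT and 1.13 ± 0.81 in TREM2-KO (SD, n = 7 and 8), and 3 of the 9 kept markers, COL1A2, DCN and LUM, were lower in TREM2-KO. In the opposite direction, TOP2A and CCNB2 of the 25 cell cycle genes rose by 0.45 and 0.31, and the folate receptor FOLR2, a marker of border-associated macrophages, rose by 1.61. It was the only 1 of 7 such markers called, but all 7 were above 0 and 5 were higher adjusted over the list alone (limma fry adjusted p = 0.0126; adjusted p = 0.113 with an estimated correlation). Of the Alzheimer risk genes other than APOE, the kindlin FERMT2 fell by 1.21, the secretase subunit PSEN2 by 0.61 and the adaptor ABI3 by 0.19, while the membrane-shaping BIN1 rose by 0.63. Outside these lists, large changes were losses of CSRP1, a LIM-domain protein (7.17 ± 9.48 against 45.1 ± 6.50 TPM), TYW3, a tRNA-modifying enzyme (0.0713 ± 0.0327 against 7.52 ± 1.22 TPM), and the growth factor PDGFA (-2.33), and a gain of NLRP2, an inflammasome-related gene (7.20 ± 1.20 against 0.780 ± 0.607 TPM). The CSRP1 values of the TREM2-KO libraries differed widely, with an SD above their mean.

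In all, 239 of 14855 genes were called between TREM2-KO and WT, 42 higher and 197 lower, and 100 of them changed at least 2-fold. Libraries with the same number deviated together in these groups by the limit of 0.1, though only 3 of 7 matched their own number best. With the number as a block in a fit of the 2 groups alone 501 genes were called, 175 higher and 326 lower. The fit of the 2 groups alone without the block called 159 genes. This was the lowest TREM2-KO count over the alternatives, and 1715 with the residual component as a covariate was the highest.

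Innate immune genes were among those lower in TREM2-R47H hMGLs than in WT. Of the 21 kept genes of TYROBP signalling, the pathway that carries the TREM2 signal, 7 fell and none rose, among them the phosphatase PTPN6 (-0.68), the kinase LYN (-0.49), CARD9 (-0.61), SIRPB1 (-0.91), GRB2 (-0.32) and VAV1 (-0.21). Limma's fry test gave adjusted p = 0.000237 for this list, 11 members were lower adjusted over the list alone, and camera's preset call was not kept (adjusted p = 0.958 with an estimated correlation). Of 27 phagocytosis and complement genes, 9 fell and 2 rose. The complement component C1QA fell from 965 ± 162 to 624 ± 178 TPM, the Fc receptor gamma chain FCER1G from 949 ± 146 to 696 ± 53.8 TPM and the inhibitory Fc receptor FCGR2B by 1.51 on the log2 scale, while SCARB1 and TIMD4 rose by 0.48 and 0.61 (fry adjusted p = 0.0694 for the list; limma camera adjusted p = 0.958 with an estimated correlation).

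Of the 19 kept members of the cytokine and NF-kB list, 6 were called lower in TREM2-R47H, 1 higher and 12 not at all. TNF fell to 4.89 ± 0.92 TPM (-1.74, limma adjusted p = 0.000152), CXCL1 by 1.88, IL1B by 1.27 and NFKBIZ by 1.37, whereas the chemokine CCL5 rose from 2.57 ± 1.75 to 15.1 ± 9.68 TPM. This list did not pass fry (adjusted p = 0.0508) or keep camera's call (adjusted p = 0.958 with an estimated correlation). IRAK4, a kinase that links Toll-like receptors to NF-kB, was near 0 in every TREM2-R47H library, at 0.11 ± 0.09 TPM against 6.34 ± 0.91 TPM in WT. Of the 10 monocyte markers, the calgranulins S100A8, S100A9 and S100A12 fell by 3.14, 3.47 and 2.20. The apolipoprotein list had 4 genes higher, among them APOC1 at 1184 ± 286 TPM and APOC2 (0.68), and the phospholipid transfer protein PLTP lower (-1.06). Of 30 retromer and endosomal sorting genes, the late endosome GTPase RAB7A (-0.34), EHD1 (-1.38), VPS29 and SNX3 fell and SNX5 rose (0.17). Among the receptors for nucleotides and migration cues, P2RY6, ADORA3 and CMKLR1 fell by 0.83, 0.66 and 0.98 within 15 members. Stromal RNA was again lower than in WT, with COL3A1, TAGLN, DCN and LUM called lower among 9 markers; with the stromal marker score as a covariate COL3A1 had a change of 0.04 and was not called. Outside the lists, FCGBP, an IgG-binding mucin-like protein, was lower (72.9 ± 52.2 against 986 ± 622 TPM), and PTGDS (1.97), CCL24 (1.80), SCIN (1.67) and the hepcidin gene HAMP (1.64) were higher. Of the other edited genes, SORL1 was higher in TREM2-R47H (0.84, limma adjusted p = 0.0209) and INPP5D lower (-0.27, limma adjusted p = 0.0345).

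The TREM2-R47H comparison called 1693 genes, 390 higher and 1303 lower, with 261 at 2-fold or more. With median-ratio scaling the split was 615 higher and 807 lower, so the balance of directions depends on the scaling. Libraries with the same number deviated together here as well, and the block in a fit of the 2 groups alone called 2728 genes, 731 higher and 1997 lower. With the stromal covariate 989 were called, of which 881 were also among the 1693 in the same direction. Over all alternatives the TREM2-R47H count ran from 989 to 4096.

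**Figure D2:**
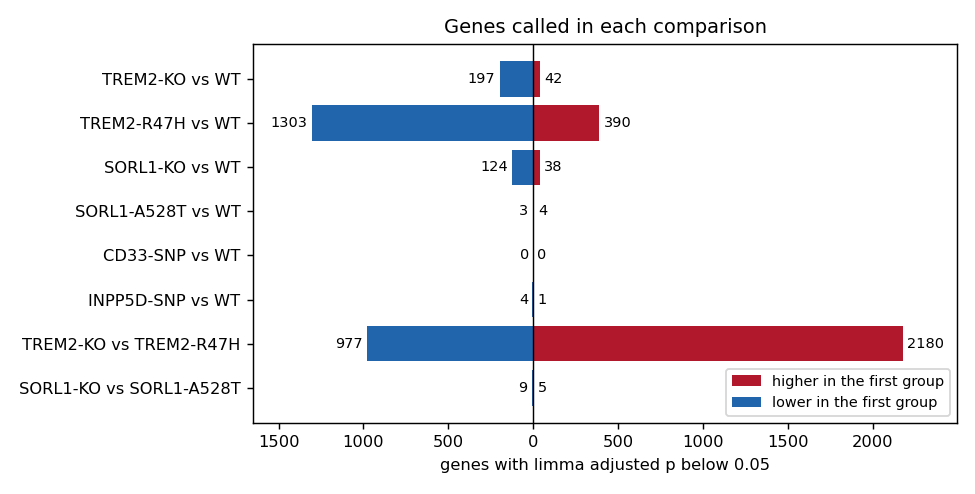
Number of genes with limma adjusted p below 0.05 (horizontal axis, linear) in each of the 8 comparisons; red bars to the right count genes higher in the first group named and blue bars to the left genes lower in it. Calls run from 0 in CD33-SNP vs WT to 3157 in TREM2-KO vs TREM2-R47H.

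The TREM2 lines were then compared with each other, since the knockout removes the receptor and the point variant alters it. Markers of other myeloid cells and phagocytic genes were higher in TREM2-KO than in TREM2-R47H: 16 of 27 phagocytosis and complement genes were higher and 2 lower (limma fry adjusted p = 0.00681), as were 7 of 10 monocyte markers (limma fry adjusted p = 0.00681) and 6 of 7 border-associated macrophage markers (limma fry adjusted p = 0.000529). With an estimated correlation none of the 3 kept camera's call (adjusted p = 0.688, 0.688 and 0.627). FCGR2B (2.65), FCGR3A (2.25), the mannose receptor MRC1 (2.16), the haemoglobin scavenger CD163 (2.08) and S100A9 (4.10) led these groups. In the opposite direction, 10 of 24 disease-associated genes were lower in TREM2-KO and 2 higher (fry adjusted p = 0.039), including SPP1 (-1.78), GPNMB (-1.79) and LPL, and 7 of 18 apolipoprotein genes were lower and 3 higher, including APOC1 (-2.84) and APOE (-1.75; limma adjusted p = 2.5e-07, two-sided exact permutation p = 0.0003, the smallest possible). EGR1, EGR2, EGR3 and FOS of the immediate early list were lower by 1.91, 2.54, 1.83 and 1.37. Of the MHC class II genes, 4 of 15 were higher in TREM2-KO, led by HLA-DPB1 (1.14) and CD74 (0.85). Camera with a preset correlation called 10 of 24 lists and fry 12, and none kept its call with an estimated correlation (lowest adjusted p = 0.627 with an estimated correlation). The comparison called 3157 genes, 2180 higher and 977 lower in TREM2-KO, with 503 at 2-fold or more; median-ratio scaling gave 1460 higher and 1413 lower.

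**Figure D3:**
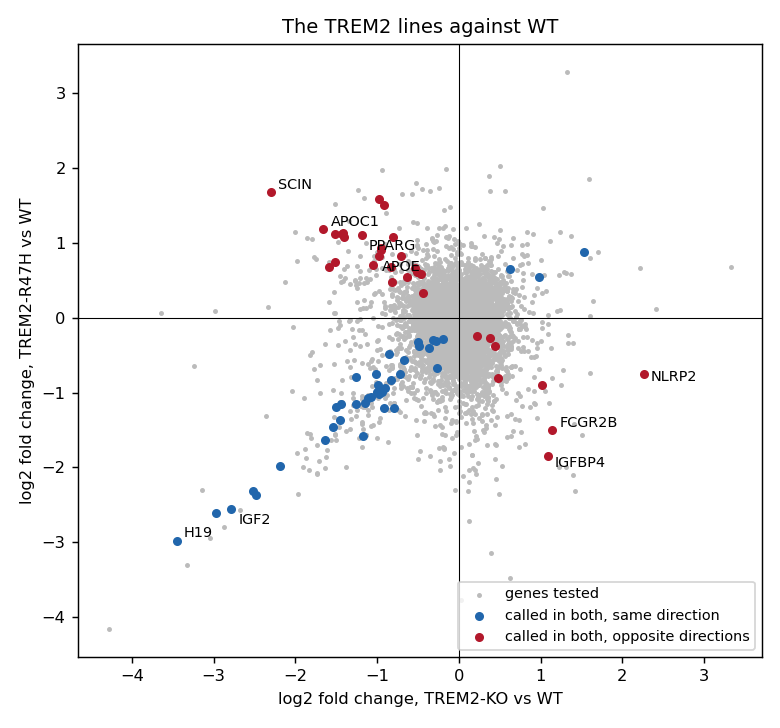
Log2 fold change of each of the 14855 genes in TREM2-R47H vs WT (vertical axis) against TREM2-KO vs WT (horizontal axis); grey points are genes tested, blue points genes called in both comparisons in the same direction and red points genes called in both in opposite directions. APOE, APOC1, SCIN and PPARG lie among 24 genes lower in TREM2-KO and higher in TREM2-R47H, and NLRP2, FCGR2B and IGFBP4 among 8 genes of the opposite kind.

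Without any of the alternatives, SORL1-KO hMGLs differed from WT in fewer genes than either TREM2 line. The order against TREM2-KO turned under some alternatives, among them the block in a fit of all libraries and arrayWeights. GPR34, a lysophosphatidylserine receptor of homeostatic microglia, rose from 252 ± 15.2 to 469 ± 96.8 TPM (0.87, limma adjusted p = 5.8e-05), the only one of 20 homeostatic genes called. The spermine synthase SMS rose from 93.5 ± 11.2 to 183 ± 18.9 TPM, HAMP from 4.11 ± 2.08 to 11.9 ± 2.03 TPM, and APOC1 from 529 ± 170 to 1012 ± 178 TPM. CAT, which encodes catalase, was almost absent, at 1.39 ± 0.91 TPM against 62.6 ± 7.59 TPM (-4.80), and the calcium-binding S100A6 fell from 20.8 ± 14.2 to 1.41 ± 0.71 TPM. Of the 30 endosomal sorting genes, RAB7A alone was called, lower by 0.23 on the log2 scale. IL1A and PTGS2 of the cytokine list fell by 0.70 and 0.46, and PTPN6 of TYROBP signalling by 0.34. None of the 32 lysosome genes was called over all genes and 5 were higher adjusted over the list alone (median 0.15); camera's preset call for that list was not kept (adjusted p = 0.337 with an estimated correlation). The unfolded protein list had 0 of 20 members called, with 3 lower adjusted over the list alone, and was lower by fry (adjusted p = 0.0409) but not with an estimated correlation (limma adjusted p = 0.26). Stromal RNA was lower, with a score of 0.97 ± 0.49 (SD, n = 7), and COL1A2, DCN and LUM were called among 9 markers (limma fry adjusted p = 0.0259; adjusted p = 0.26 with an estimated correlation). H19, IGF2 and FMOD, outside that list, were lower too. The comparison called 162 genes, 38 higher and 124 lower, with 50 at 2-fold or more. With the stromal covariate 18 genes were called in SORL1-KO, 8 higher and 10 lower, and with libraries 5 and 6 averaged 35. The fit of the 2 groups alone called 52, and 67 were called without a filter. Other alternatives called more, 420 with libraries 1 to 3 alone, 673 with arrayWeights, 735 with the block in a fit of all libraries and 1242 with the residual component as a covariate.

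SORL1-A528T, a missense variant of SORL1, had 7 genes called against WT, 4 higher and 3 lower, and 884 genes had an unadjusted p below 0.05. The higher genes were TFE3, a transcription factor of lysosomal genes (110 ± 4.41 against 66.0 ± 3.27 TPM), the nucleotide sugar transporter SLC35A2 (35.8 ± 3.21 against 21.2 ± 2.62 TPM), GRIPAP1 (52.8 ± 5.58 against 33.8 ± 1.85 TPM) and the lymphocyte adaptor SASH3 (301 ± 62.4 against 202 ± 10.9 TPM), all on the X chromosome. In INPP5D-SNP, TFE3, GRIPAP1 and SASH3 were at 115 ± 16.6, 54.3 ± 7.07 and 286 ± 7.27 TPM (SD, n = 2). The GTPase-activating TBC1D15 fell from 24.1 ± 3.62 to 12.6 ± 2.68 TPM, and EHD2 and MME, the other lower genes, were lower in all 4 lines with 7 or more libraries and are named after their values were seen. The endothelial and stromal markers had a median change of -2.58, with none of 9 called over all genes and 9 lower adjusted over the list alone (fry adjusted p = 0.042; limma adjusted p = 0.102 with an estimated correlation), and the score was 1.09 ± 0.44 (SD, n = 7). Counts of called genes ran from 3 to 127 across the alternatives.

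SORL1-KO and SORL1-A528T differed in 14 genes, 5 higher and 9 lower in SORL1-KO, with 4 at 2-fold or more. SORL1 itself was lower by 1.20 on the log2 scale (limma adjusted p = 0.0256; two-sided exact permutation p = 0.000583, the smallest possible). CAT (-4.78), MMADHC, a gene of vitamin B12 metabolism (51.6 ± 2.27 against 101 ± 3.04 TPM), TFE3 (-0.84), SLC35A2 (-0.90), GRIPAP1 (-0.72) and SASH3 (-0.65) were lower, and SMS (0.82), GPR34 (0.74) and TBC1D15 (0.87) higher. Of the 2 lists called by camera with its preset correlation, neither kept the call (lowest adjusted p = 0.565 with an estimated correlation), and fry called none. Same-numbered libraries of these lines deviated together, and with the block in a fit of the 2 groups alone 74 genes were called, 25 higher and 49 lower.

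CD33-SNP and INPP5D-SNP had 2 libraries each. No gene was called by limma in CD33-SNP, where 621 had an unadjusted p below 0.05, and 0 of 24 lists kept camera's call with an estimated correlation (lowest adjusted p = 0.521). Without a filter on low values 209 genes were called there, all higher. INPP5D-SNP had 5 called genes, not all of which stayed called when either of its 2 libraries was left out. Among them LLPH was at 16.6 ± 1.23 against 38.9 ± 2.77 TPM in WT and the heat shock gene HSPA1A at 9.21 ± 9.57 against 40.6 ± 8.73 TPM (SD, n = 2 and 7), while TFE3 was higher, at 115 ± 16.6 TPM. The stromal score was 1.44 ± 0.22 in CD33-SNP and 3.82 ± 1.03 in INPP5D-SNP (SD, n = 2 each), the latter above the WT mean. The INPP5D-SNP count ran from 4 to 1837 across the alternatives.

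Whether the lines shared changes was examined across the 4 lines with 7 or more libraries. 164 genes were called in the same direction in at least 2 lines, 36 higher and 128 lower. 16 were lower in at least 3, among them EHD2, MME, the stromal markers DCN and LUM, and PTPN6 of TYROBP signalling. EHD2, a membrane-remodelling ATPase, and MME, a membrane endopeptidase that degrades amyloid beta, were lower in all 4. By limma no gene was called in all 4 with pseudocounts of 0.1 or 5 TPM, without a filter, with the filter at 5 TPM, in fits of the 2 groups with or without the block, without the 3 libraries that stand apart, with libraries 5 and 6 averaged, or with the stromal covariate. The mean stromal score was lower than in WT in each of these 4 lines. TREM2-R47H and SORL1-KO shared the most, 29 genes higher and 105 lower, against 1.00 and 10.9 for independent lists of the same lengths. APOC1, HAMP, SMS, GPR34 and RUNX2 were among those higher. SMS and GPR34 lie on the X chromosome, and changes of X genes that may have arisen in single clones are weighed below. TREM2-KO and TREM2-R47H shared 3 higher and 36 lower, against 1.10 and 17.3. Because all lines were set against the same WT libraries, some sharing arises with no effect at all; in 100 simulated sets of unchanged groups, 1 set held any gene shared by 2 lines, and that set held 2040, more than were observed. With WT libraries 1 to 3 used for one line and 4 to 7 for the other, TREM2-R47H and SORL1-KO shared 9 higher and 46 lower, and TREM2-KO and TREM2-R47H 0 and 4. The stromal score ran from 0.55 to 3.15 in WT libraries 1 to 3 and from 1.53 to 4.90 in 4 to 7. The split counts are therefore not free of differences in WT composition. The covariance of fold changes across genes, which are not independent replicates, was 0.0636 for TREM2-R47H with SORL1-KO against 0.0241 ± 0.0162 in the simulations (SD), and 0.0101 for TREM2-KO with TREM2-R47H against 0.0243 ± 0.0167. The simulations dealt residuals out at random and so leave out the correlation between same-numbered libraries of TREM2-KO or TREM2-R47H and WT, which changes the covariance to be had with no effect. The correlations were 0.64 and 0.10, against simulated means of 0.50 and 0.52. With the stromal covariate 43 genes were shared in at least 2 lines, 39 with libraries 5 and 6 averaged, 57 with fits of the 2 groups alone and 75 without a filter. The count was 203 with WT libraries 1 to 3 used for the TREM2 lines and 4 to 7 for the SORL1 lines, 439 with libraries 1 to 3 alone, 673 with the block in a fit of all libraries, 683 with arrayWeights and 963 with the residual component.

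In the lines with 7 or more libraries, certain genes were far lower in every library of a single edited line than in any library of any other group, away from the edited gene; these were singled out after their values were seen. In TREM2-KO they were TYW3 and CRYZ (quinone reductase), which lie head to head on chromosome 1 (74733152 to 74766678 and 74705482 to 74733408, GRCh38). In TREM2-R47H they were IRAK4 and PUS7L, a pseudouridine synthase, head to head on chromosome 12 (43758944 to 43789543 and 43718993 to 43758817), with PUS7L at 0.033 ± 0.045 against 2.31 ± 0.94 TPM in the other groups. In SORL1-KO they were CAT (chromosome 11, 34438925 to 34472062) and the zinc finger gene ZNF717 (chromosome 3, 75678660 to 75785583), a gene with close relatives whose reads may be split. CAT was also called lower in TREM2-KO, at 29.2 ± 19.9 TPM (SD, n = 8), a change of -1.29. In that line libraries 4 and 8 were at 59.9 and 62.2 TPM and the other 6 between 14.5 and 22.6 TPM. The nearest kept genes on each side of CAT, NAT10 and PDHX, had changes of -0.02 and 0.06 in SORL1-KO, and TWF1 next to IRAK4 had -0.09 in TREM2-R47H.

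**Figure D4:**
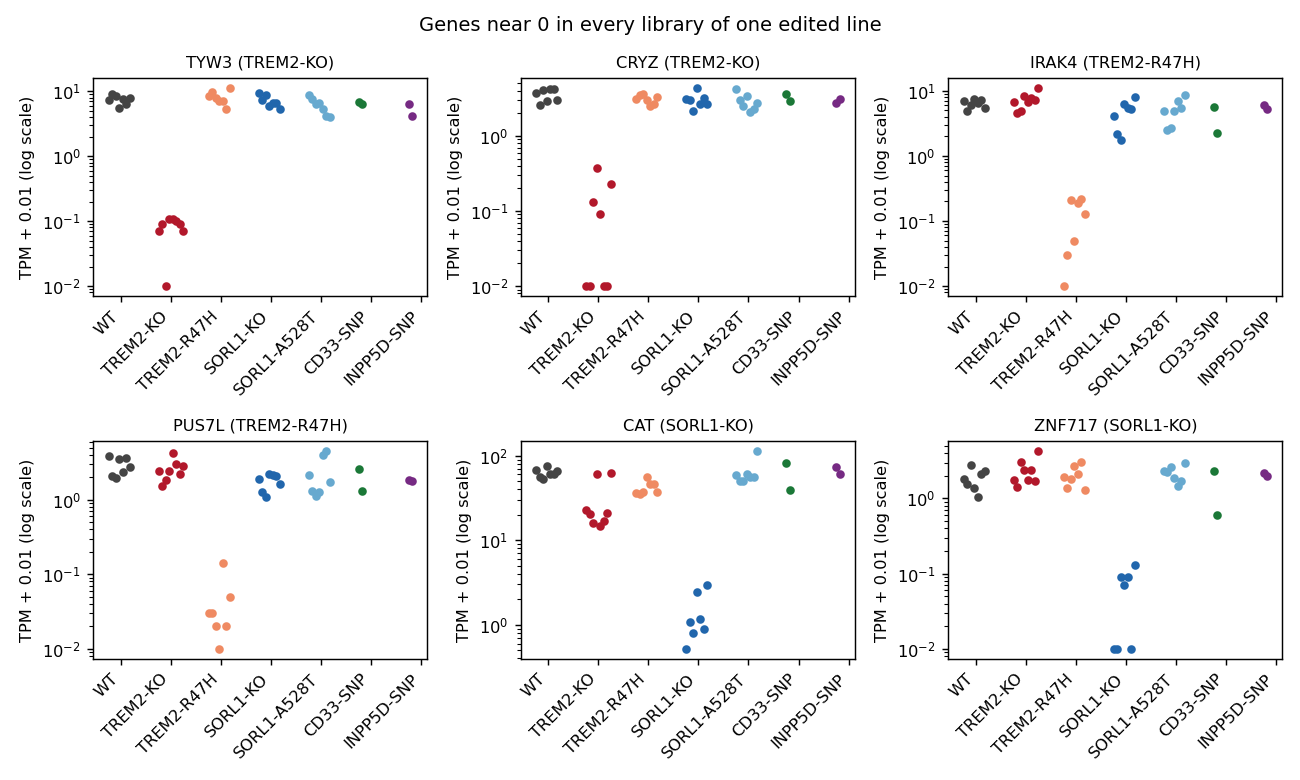
TPM + 0.01 of 6 genes (vertical axes, logarithmic) in each of the 40 libraries, by group, with the line that lost the gene named above each panel; points are libraries placed in order of their number. Every library of the named line lies below every library of the other groups.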

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

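The tests of the 3 patterns weighed below were chosen only after the results were seen, and the random splits of the libraries were fixed beforehand.

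In 12 of 89 tests, each of 1 measure in 1 group of 7 or 8 libraries, 1 library lay farther from the others than Dixon's 95 percent value allows. Chance gives about 1 in 20 for normally spread values. The tests reuse the same libraries, mostly on TPM of named genes, so that share is only a guide. WT replicate 4 was highest for S100A9 (ratio of gap to range 0.753; 1915 TPM against 82.6 to 535 in the others), FOLR2 (0.690; 22.3 against 4.13 to 9.77), C1QA (0.645; 1303 against 830 to 998) and LPL (0.6004; 125 against 48.5 to 78.9). TREM2-R47H replicate 4 was highest for TREM2 (0.706; 646, and 391 in the lowest), SORL1 (0.739; 80.2 against 52.1 to 59.4) and S100A9 (0.763; 107, and 37.6 in the next). SORL1-A528T replicate 7 was lowest for CD33 (0.789; 25.1 against 55.3 to 63.4) and highest on residual component 1 (0.633). TREM2-KO replicate 8 was highest for INPP5D (0.619; 161 against 120 to 136), TREM2-KO replicate 3 lowest for TYW3 (0.6; listed at 0 against 0.06 to 0.10), and SORL1-KO replicate 7 highest for GPR34 (0.58; 672 against 401 to 514).

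32 genes were called in opposite directions in TREM2-KO and TREM2-R47H against WT, which differ by the direct limma contrast of the 2 lines. Lower in TREM2-KO by that contrast (log2) were SCIN (-3.97), APOC1 (-2.84), GLDN (-2.64), CSPG4 (-2.56), EGR2 (-2.54), MYOZ1 (-2.54), CHI3L1 (-2.48), ENPP1 (-2.42), PPARG (-2.29), WIPF3 (-2.26), FABP3 (-2.26), LINC01010 (-1.89), BIRC7 (-1.88), USP2 (-1.85), DLX3 (-1.80), APOE (-1.75), MPDZ (-1.54), APOC2 (-1.51), DOP1B (-1.30), LANCL3 (-1.20), APOC4-APOC2 (-1.17), WARS1 (-1.12), DBI (-1.04) and RASA1 (-0.77). Higher in TREM2-KO were NLRP2 (3.01), IGFBP4 (2.93), FCGR2B (2.65), TBL1X (1.92), SIGLEC10 (1.28), NHERF1 (0.82), HMGB2 (0.66) and YIF1B (0.47). Both changes share the WT libraries, which moves them in the same direction and not apart.

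Random splits of the same libraries tested whether chance can give the counts. For called genes, the real split was the only 1 of 100 with as many in each comparison with 7 or more libraries a group. Real counts (highest other) were 239 (106) for TREM2-KO, 1693 (337) for TREM2-R47H, 162 (135) for SORL1-KO and 7 (2) for SORL1-A528T. Between lines they were 3157 (2401) for TREM2-KO against TREM2-R47H and 14 (6) for SORL1-KO against SORL1-A528T. The 164 shared genes (highest other 1) and the 2 shared by all 4 lines (highest other 0) were also reached only by the real grouping. Those regroupings mixed WT with all 4 lines, so they cannot tell sharing from separate changes in each line. Independent lists of the same lengths would alone share 17.3 lower genes between TREM2-KO and TREM2-R47H. With 100 splits, a share below 1 in 100 cannot be seen. The splits also treat libraries as independent, which the labels do not establish. The counts of called genes therefore argue against chance but do not exclude it. In simulated sets with no change, however, 1 of 100 held shared genes, 2040 of them, and the cause was not tested. The split with 2401 genes put libraries 1 to 3 of both TREM2 lines together, along with TREM2-R47H replicates 4 and 7. Residual correlations of same-numbered libraries of these lines ran from 0.09 to 0.54, so the numbers did not pair them by the limit of 0.1. A structure by library number is therefore not settled here. With the number as a block in a fit of the 2 groups alone 3940 genes were called. Among the 64 splits that part every same-numbered pair, the highest others were 21 for TREM2-KO, 305 for TREM2-R47H and 4 for SORL1-KO against SORL1-A528T. For lists called by camera with its preset correlation, chance cannot be excluded: 29, 59, 50, 36, 39 and 90 of 100 splits called as many in the same order of comparisons (real 11, 8, 10, 11, 10 and 2; highest other 17, 15, 17, 18, 18 and 17).

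In the lines with 7 or more libraries, a limit set after the results were seen, 6 genes at 4 loci (TYW3 with CRYZ, IRAK4 with PUS7L, CAT and ZNF717) were lost in every library of 1 edited line, and CAT was also called lower, though not lost, in TREM2-KO (-1.29). Loss of a wider segment is argued against by the median change of the 4 nearest kept genes on each side (-0.041). Dilution by RNA from other cells is argued against by the homeostatic list. Its lowest median over these lines was -0.13 (SD of its members 0.36) against -1.42 for the weakest lost gene. Of 100 random regroupings 1, the real one, gave as many lost genes (highest other 0). The rule for a lost gene was set after the values were seen in the real groups, so these regroupings cannot weigh against chance. Batches shared by number are argued against in TREM2-KO and TREM2-R47H, whose numbers pair with WT by the limit of 0.1. Over all lines, genes found lost without the libraries of a number differed from WT in that number by -0.91 or below (highest SD of a gene in WT 0.31). The numbers do not pair SORL1-KO with WT, so for CAT and ZNF717 these differences cannot decide. A batch holding all libraries of 1 line cannot be told apart from the line. A promoter shared by a divergent gene pair may account for part and stays open: 2 of 4 loci have such a neighbour within 1 kb against 1944 of 12132 kept protein-coding genes (Fisher's exact p = 0.123), and a definition without overlap of the starts, used first, gave 1 of 4 (p = 0.305). IRAK4 was below 1 TPM in 7 of 7 TREM2-R47H libraries, so its loss and the TREM2 edit cannot be told apart as sources of the lower cytokine and NF-kB genes, and changes that arose in a clone during editing or growth stay open.

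The 4 genes higher in SORL1-A528T all lie on the X chromosome, against 3.26 percent of kept genes, but SLC35A2, GRIPAP1 and TFE3 lie within 140 kb, where PIM2 and OTUD5 between them were also higher though not called (17.1 and 48.1 TPM against 7.54 and 32.0 in WT); counted as 2 loci, Fisher's exact test, prompted by the observation itself, gave p = 0.00105. The mean log2 value of the 4 genes was 6.43 and 6.49 in INPP5D-SNP, within the 6.39 to 6.64 of SORL1-A528T, and 6.14 in CD33-SNP replicate 2 and 6.15 and 6.24 in TREM2-KO replicates 5 and 6, all above the 5.78 to 5.94 of WT. In TREM2-R47H, TFE3, SLC35A2 and GRIPAP1 were called higher (88.1, 34.9 and 42.7 TPM) while SASH3 was at 164 TPM against 202 in WT, so the pattern is not confined to the line with this SORL1 edit and the 4 genes did not always move together. With genes counted singly, 25 of 390 called higher and 36 of 1303 called lower in TREM2-R47H lie on X. Fisher's exact test of the higher genes, adjusted over 6 lines, gave p = 0.00379 there and 0.189 for SORL1-KO (3 of 38, SMS and GPR34 among them). An additional copy of the whole chromosome is argued against by the median change of the kept X genes (-0.018). When 4 X genes were chosen anew without the libraries of a number, they were TFE3, SLC35A2 and GRIPAP1 with GPC4 or OTUD5. SASH3 was not among them. The genes so chosen differed in the number left out by 0.54 or more (SD of their mean in WT 0.058). The numbers do not pair SORL1-A528T with WT, so these differences cannot test a batch shared with WT by number. A change of some X genes that arose in single clones may account for the pattern and stays open, as does a batch holding all libraries of a line, and no biological explanation was tested.

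APOE was called higher than in WT in TREM2-R47H and, in SORL1-KO, passed the exact test and limma under 3 alternatives (the block in both fits and the residual component). Dilution of WT RNA by RNA of other cells is argued against, since APOE rose beyond the median of the lysosome list by 0.65 in the line where the excess was smaller. Numbered batches are argued against in TREM2-R47H by APOE differences between libraries of the same number, above 0 in 6 of 7 (two-sided exact sign-flip permutation p = 0.0312). In SORL1-KO such differences were above 0 in 7 of 7 (two-sided exact sign-flip permutation p = 0.0156). The numbers do not pair SORL1-KO with WT, so there they cannot test numbered batches. A culture state that goes with stromal RNA in WT stays open: over 7 WT libraries APOE and the stromal score had r = -0.74 (two-sided exact permutation p = 0.0528), r = -0.18 without the 2 farthest, and the covariate reduced the change from 0.70 ± 0.23 to 0.39 in TREM2-R47H and from 0.80 to 0.42 in SORL1-KO. An effect of the edits is a further open explanation.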

How the results depend on the processing

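The stromal covariate, the averaging of libraries 5 and 6, the block in fits of 2 groups, libraries 1 to 3 alone and the fit without 3 libraries that stand apart were chosen after the data were seen. The limit set by sequencing depth could not be computed from TPM without counts, and values under about 1 TPM are compressed by the pseudocount. Of 4130 values for 259 named calls, 419 were no longer called and 2 changed sign: with the stromal covariate COL3A1 (0.037) and SPARC (0.044) in TREM2-R47H, where COL3A1 is itself part of the score. APOE and each line's own edited gene against WT are not in this count. TREM2 in TREM2-KO kept its direction and its call under every alternative run. Except where a construction is named, the cause was not tested.

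Called lists changed with the correlation assumed between their genes: with an estimated correlation 2 were called in TREM2-KO and 0 in each of the other 7 comparisons, and with fry 5 in TREM2-KO, 1 in TREM2-R47H, 2 in SORL1-KO, 1 in SORL1-A528T and 0 in CD33-SNP, INPP5D-SNP and SORL1-KO against SORL1-A528T.

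With a pseudocount of 0.1 TPM, SORL1-A528T had 4 genes, SORL1-KO against SORL1-A528T 1 list and all 4 lines shared 0 genes; with 5 TPM, SORL1-A528T had 4, INPP5D-SNP 8 and the 4 lines shared 0. Without a filter on low values, which raises the genes tested from 14855 to 35502, APOE in TREM2-R47H (0.70, limma adjusted p = 0.0831) and SORL1 in SORL1-KO (-0.96, limma adjusted p = 0.0942) were not called, SORL1-KO had 67 genes, SORL1-A528T 4, CD33-SNP 209, INPP5D-SNP 373, TREM2-KO against TREM2-R47H 16 lists, 75 genes were shared and 0 by all 4 lines. With TPM of 5 or more in 7 libraries, and with 1 or more in 2 libraries, SORL1-KO against SORL1-A528T had 1 list, and with the former the 4 lines shared 0 genes.

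With median-ratio scaling SORL1 in SORL1-KO was not called (-0.93, limma adjusted p = 0.0536) and SORL1-A528T had 12 genes. Quantile normalization gave 16 there, and neither APOE in TREM2-R47H (0.60, limma adjusted p = 0.0893) nor SORL1 in SORL1-KO (-0.92, limma adjusted p = 0.0529) was called. In fits of the 2 groups alone, which have fewer libraries for the spread, TREM2-KO had 159 genes, SORL1-KO 52, SORL1-A528T 4 and INPP5D-SNP 489, APOE in TREM2-KO was not called (-1.05, limma adjusted p = 0.0748), SORL1-KO against SORL1-A528T had 4 lists, and 57 genes were shared, 0 by all 4 lines.

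The number as a block in the fit of all libraries gave 587 genes in TREM2-KO, 2906 in TREM2-R47H, 735 in SORL1-KO, 127 in SORL1-A528T, 38 in CD33-SNP, 1567 in INPP5D-SNP and 24 between the SORL1 lines, 673 shared and 49 in all 4; APOE was called in SORL1-KO (0.80) and turned to -0.13 in INPP5D-SNP. The block in fits of 2 groups gave 501, 2728, 100 and 4 genes in TREM2-KO, TREM2-R47H, SORL1-KO and SORL1-A528T, 74 genes and 6 lists between the SORL1 lines, APOE called in SORL1-KO (0.80) and 0 genes in all 4. The numbers pair TREM2-KO and TREM2-R47H with WT and the SORL1 lines with each other, not the other comparisons.

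With arrayWeights TREM2-KO had 634 genes and 7 lists, TREM2-R47H 4096, SORL1-KO 673, SORL1-A528T 55, INPP5D-SNP 31, TREM2-KO against TREM2-R47H 4768, the SORL1 lines 4 lists, 683 genes were shared and 7 by all 4, and TREM2 in TREM2-R47H turned to -0.013. With the residual component the gene counts were 1715, 3704, 1242, 99, 99 and 1837 for the 6 lines against WT in the order of the report, 5920 and 24 between lines, with 1 list between the SORL1 lines, APOE called in SORL1-KO (0.80), 963 shared and 20 in all 4; a component taken from the residuals makes the residual spread smaller by construction.

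Leaving out 1 library, with the lone library assumed to vary like the others, gave 3 to 11 lists in CD33-SNP and 7 to 14 in INPP5D-SNP, and APOE between 0.0017 and 0.72 in CD33-SNP and between -0.17 and 0.27 in INPP5D-SNP. Without the 3 libraries that stand apart, TREM2-KO had 7 lists, SORL1-A528T 6, the SORL1 lines 1, INPP5D-SNP 10 genes and all 4 lines 0. With libraries 5 and 6 averaged SORL1-KO had 35 genes, SORL1-A528T 3, 39 were shared and 0 by all 4, APOE in TREM2-R47H was not called (0.67, limma adjusted p = 0.0737), and TREM2 in TREM2-R47H (-0.028) and APOE in INPP5D-SNP (-0.034) changed sign. With the stromal covariate TREM2-R47H had 989 genes, SORL1-KO 18, SORL1-A528T 4, 43 were shared and 0 by all 4, APOE in TREM2-R47H was not called (0.39, limma adjusted p = 0.387, range over alternatives 0.000476 to 0.387), and TREM2 in TREM2-R47H (-0.066) and SORL1 in SORL1-A528T (-0.16) changed sign. Libraries 1 to 3 alone gave 3524 genes in TREM2-R47H, 420 in SORL1-KO, 42 in SORL1-A528T, 5 lists between the SORL1 lines and 439 shared genes; APOE was not called in TREM2-KO (-0.83, limma adjusted p = 0.145) or TREM2-R47H (0.42, limma adjusted p = 0.264), and TREM2 in TREM2-R47H was -0.17. With WT libraries split between the TREM2 and SORL1 lines, 1 gene was lower in all 4.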

Other observations

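The values here were chosen after the data were seen and carry no test of a cause. Libraries 5 and 6 were the closest pair in each of the 5 large groups, with a robust SD of log2 differences between 0.0733 (SORL1-KO and TREM2-R47H) and 0.0881 (WT) against group medians between 0.171 and 0.275, and 0 pairs held identical values. Without read counts these distances cannot be set against sampling noise. The first residual component held 31.2 percent of the variance left after the groups, the next 10.3 and 6.09 percent, and on it TREM2-KO replicate 8, SORL1-KO replicate 7 and SORL1-A528T replicate 7 had the highest values (0.384 to 0.416; next TREM2-KO replicate 4, 0.308).

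Residuals of same-numbered libraries correlated by 0.11 to 0.31 between TREM2-KO and WT, 0.14 to 0.28 between TREM2-R47H and WT, and 0.31 to 0.78 between SORL1-KO and SORL1-A528T. In SORL1-KO with WT the range was -0.11 to 0.29 and in SORL1-A528T with WT -0.08 to 0.43. Of 7 shared numbers, the best match was the library's own number in 3, 4, 3, 4 and 3 of these comparisons in that order. By that count SORL1-KO with WT, not taken as paired, did as well as TREM2-R47H with WT. The limit of 0.1 therefore parts these comparisons only loosely. COL1A1 ran from 0.49 to 666 TPM among the WT libraries and was at 142 and 476 TPM in the INPP5D-SNP libraries. Over the 40 libraries, mitochondrial genes held 10.8 to 14.1 percent of TPM and the 10 highest genes 12.3 percent or more.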
